A study of Mus musculus with 8 samples.

How the data were processed

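Total RNA of mouse hippocampus was labelled with Cy3 after removal of ribosomal RNA, with primers along the whole transcript, and hybridized to Agilent arrays, per the labels' protocols. The samples fall into 4 propofol and 4 vehicle arrays by their titles. The spot signals are background-subtracted intensity values written by Agilent Feature Extraction 11.0.1.1, per the file headers. The deposited value table holds log2 intensity values for 22032 probes. Its columns have nearly the same distribution, with medians from 8.66 to 8.80, and each correlates at 0.9997 or more with the log2 spot signal of its array; how the authors normalized it was not stated in the files used here.

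From the spot files, control spots and 15 probes named as negative controls were left out. The remaining 61200 spots were taken as log2 of the processed signal minus the 75th percentile of their array. Spots marked as non-uniformity or population outliers, 0.413% of them, were dropped, and spots of one probe were averaged. No spot was saturated. A probe was kept if it was well above background on at least 4 of the 8 arrays, and 87 probes with fewer than 2 unflagged arrays in a group were then dropped. Propofol was compared with vehicle for each probe with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. A looser rule counted probes at an unadjusted p under 0.05 with at least a 1.5-fold difference. Single values of the arrays were compared with exact two-sided permutation tests over the 70 assignments of the 8 arrays, in R and in Python 3.11.15 with scipy 1.17.1.

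Gene names came from the accessions in the spot files, matched without versions to a RefSeq gene table of assembly GRCm38.p6. All 15 accessions matched, and each of these genes had 1 probe. The files' own grid names an older mouse build, so no coordinates are given. The other probes have manufacturer identifiers only. The rule for named genes, fixed before the data were examined, took genes past the threshold with groups that do not overlap and a mean above the median probe, filled up to 12 per direction by the smallest unadjusted p. It also took up to 4 members of each fixed list, of which only Hsp90ab1 and Gapdh had a named probe. Some genes were always to be given, and none of those had a named probe. Without names the fill was held to 2 probes per direction, and all 15 genes with a name are reported. The 31 gene lists fixed in advance needed 5 tested members and were not testable.

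The fit was tested on simulated data made from the means and spreads of 46848 probes for the comparison of propofol with vehicle, with 200 probes changed by known folds in each of 5 runs. With independent noise, 3.58% of the 1.5-fold changes, 30.7% of the 2-fold changes and 79.7% of the 4-fold changes passed the adjusted threshold. With the residuals of the real arrays in place of that noise, the shares were 0% at 1.5-fold, 2.39% at 2-fold and 70% at 4-fold. These residuals were centred within each group, scaled up and not resampled, so unchanged probes did not differ between the groups. The lower shares follow at least in part from that construction and do not measure the power of the real arrays.

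Alternatives were other normalizations, a normexp background correction, the deposited values, other filters on dim probes, an intensity trend, array weights, a replicate block, an equal-variance test without shared variance and leaving out each array. Covariates from the control spots, and the fit without vehicle replicates 2 and 3, were added after seeing the data. The workbook sheets hold plot titles and captions and were not used here.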

Results

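Hippocampal RNA from 7-day-old mice was profiled on 8 one-colour Agilent arrays, 4 from pups given propofol, a GABA-A receptor acting anaesthetic, and 4 from pups given its lipid vehicle. Each pup received 50 mg/kg of propofol or of intralipid, with 3 h of exposure and a further 3 h of washout before the hippocampus was taken. The comparison of propofol with vehicle asks which transcripts of the developing hippocampus differ at the end of that washout. The 75th percentile of the spot signal, the measure of array brightness, ran from 656 to 991 units on the vehicle arrays and from 871 to 1006 units on the propofol arrays. Of 60915 non-control probes, 41859 were well above background on all 8 arrays and 47777 were tested. The number of arrays limits the precision, and the median 95% interval of a probe reached 1.34-fold to either side. The labels do not say whether an array holds 1 animal or a pool, and give no sex.

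The 15 probes that carry a RefSeq accession were the only tested probes with a gene name, and none of these 15 genes passed the test between propofol and vehicle. The largest difference among them was in Tfrc, the transferrin receptor that brings iron into cells. Its level was 5.13 ± 0.31 (SD, n = 4) on the log2 scale in propofol and 4.70 ± 0.25 (SD, n = 4) in vehicle, a 1.35-fold higher mean with a 95% interval from 0.995 to 1.83. That difference had an adjusted p of 0.638 in limma, and 3 of the 4 propofol arrays lay above the vehicle mean. Actb, the cytoskeletal beta-actin gene, was lower in propofol by a log2 difference of -0.24 (SE 0.17, adjusted p = 0.772 in limma), with all 4 propofol arrays below the vehicle mean. Ldhal6b, a lactate dehydrogenase-like gene near the dim end of the arrays, differed by -0.20 (SE 0.14, adjusted p = 0.774 in limma).

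Among the chaperone and metabolic genes, the differences were smaller than the 95% intervals around them. Hsp90ab1, a cytosolic chaperone of the HSP90 family and the one named member of the heat shock list, differed by 0.13 (SE 0.11), with 4 of 4 propofol arrays above the vehicle mean. Gapdh, a glycolytic enzyme and the one named member of the hypoxia and glycolysis list, differed by 0.04 (SE 0.12), an interval from 0.857-fold to 1.23-fold. Hprt, of purine salvage, differed by 0.14 (SE 0.14), and Gusb, a lysosomal enzyme, by 0.14 (SE 0.14). B2m, the light chain of class I histocompatibility molecules, differed by 0.13 (SE 0.15). Without propofol replicate 1 the differences of Hprt, Gusb and B2m were 0.24, 0.23 and 0.24, and without propofol replicate 3 they were 0.09, 0.05 and 0.06. G6pd2, a glucose-6-phosphate dehydrogenase gene, differed by -0.11 (SE 0.25), and Gk, glycerol kinase, by 0.04 (SE 0.25). Both signs turned with 1 array left out, to 0.03 for G6pd2 without vehicle replicate 4 and to -0.10 for Gk without vehicle replicate 1.

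The remaining named genes were Tuba1b of the microtubule, the prolyl isomerase gene Ppia, the transcription factor gene Tbp, the ribosomal protein gene Rpl13a and the RNA-binding protein gene Nono. Their log2 differences were 0.07 for Tuba1b, -0.06 for Ppia, 0.05 for Tbp, -0.02 for Rpl13a and 0.0030 for Nono, and the signs for Nono, Ppia and Rpl13a depended on the scaling. In all, 10 of the 15 genes had a higher and 5 a lower mean in propofol, with 0 genes past the threshold over all probes or adjusted over the list alone (smallest adjusted p = 0.794 over the list, limma). The 95% interval lay within 1.5-fold either way for 11 of the genes and within 2-fold for all 15. Each of these genes was printed on 20 spots per array, and the median SD between spots of a gene was 0.031 on the log2 scale, against 0.16 between arrays of a group. Probe sequences were not used, so signal from related genes or pseudogenes of Gapdh, Actb, Ppia, Rpl13a or G6pd2 was not separated.

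**Figure D1:**
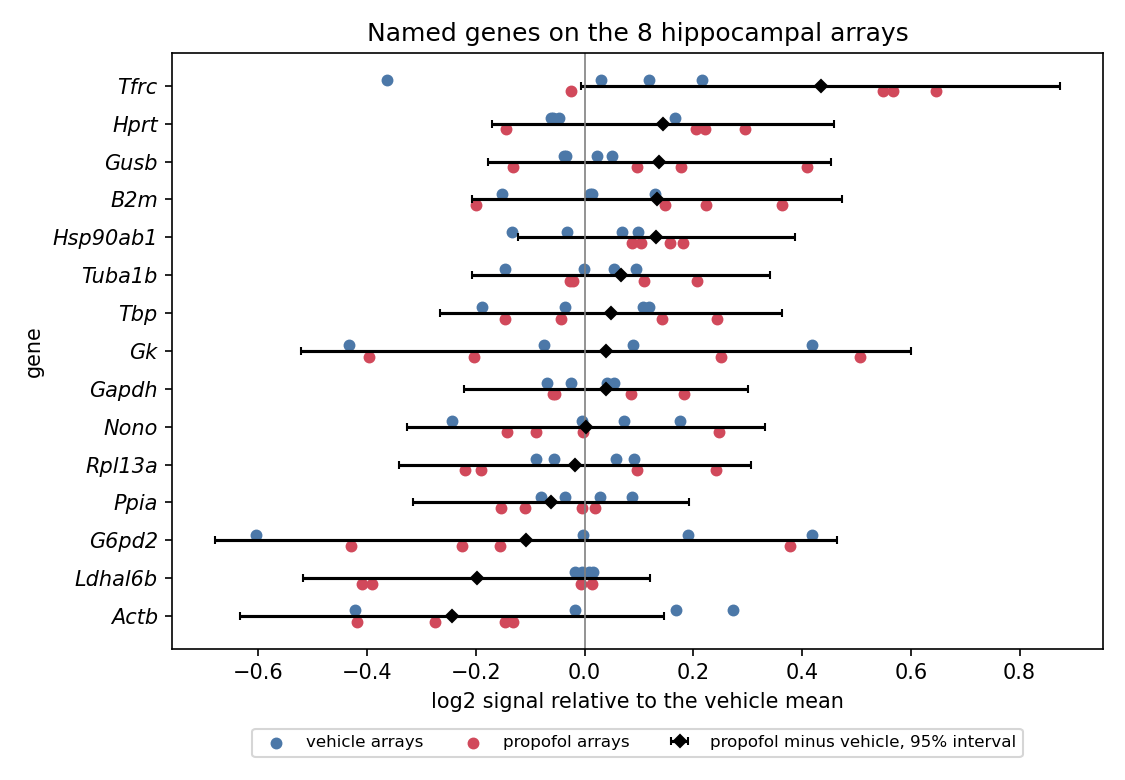
Log2 signal of the 15 named genes on the 4 vehicle and 4 propofol arrays, each relative to the vehicle mean of that gene, with the difference of the group means and its 95% interval from limma (diamond and bar). The difference is largest for Tfrc, at 0.43, and every interval includes 0.

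Over all 47777 tested probes, 0 passed an adjusted p of 0.05 in limma, with 3756 at an unadjusted p under 0.05, or 7.86% of the probes. The smallest adjusted p was 0.196. At an unadjusted p under 0.05 and a difference of at least 1.5-fold, 627 probes were higher and 651 lower in propofol. This balance turned with the scaling, to 772 higher and 429 lower with quantile normalization and to 532 higher and 767 lower with the 75th percentile over probes well above background on all 8 arrays, and to 464 higher and 1034 lower without propofol replicate 4. The groups did not overlap at 5.42% of the probes, where chance gives 2.86% on average over splits of the 8 arrays into 4 and 4. How that share varies between splits was not computed, so it is not shown to be an excess. By limma at an unadjusted p under 0.05, 8 other splits had more probes than the real one. The files do not pair the other probes with genes, so the 2 probes in each direction chosen by the rule for named genes are given by their identifiers. The rule takes only probes whose groups do not overlap, so that separation is no added support for them. Probe ASMM10P015584 was higher in propofol by 1.82 on the log2 scale (SE 0.21, adjusted p = 0.196 in limma), a 3.53-fold difference. Probe ASMM10P041006 was higher by 1.12 (SE 0.14, adjusted p = 0.243 in limma). Probe ASMM10P033423, the only one of these 4 that belongs to the mRNA probes of the deposited value table, had a mean of 3.34 ± 0.32 (SD, n = 4) in vehicle and 1.45 ± 0.32 (SD, n = 4) in propofol, a log2 difference of -1.89 (SE 0.21, adjusted p = 0.196 in limma). Probe ASMM10P039419 differed by -1.49 (SE 0.15, adjusted p = 0.196 in limma). With a normexp background correction, 3 probes passed the threshold, ASMM10P015584, ASMM10P033423 and ASMM10P039419, each with an adjusted p of 0.0285 in limma.

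**Figure D2:**
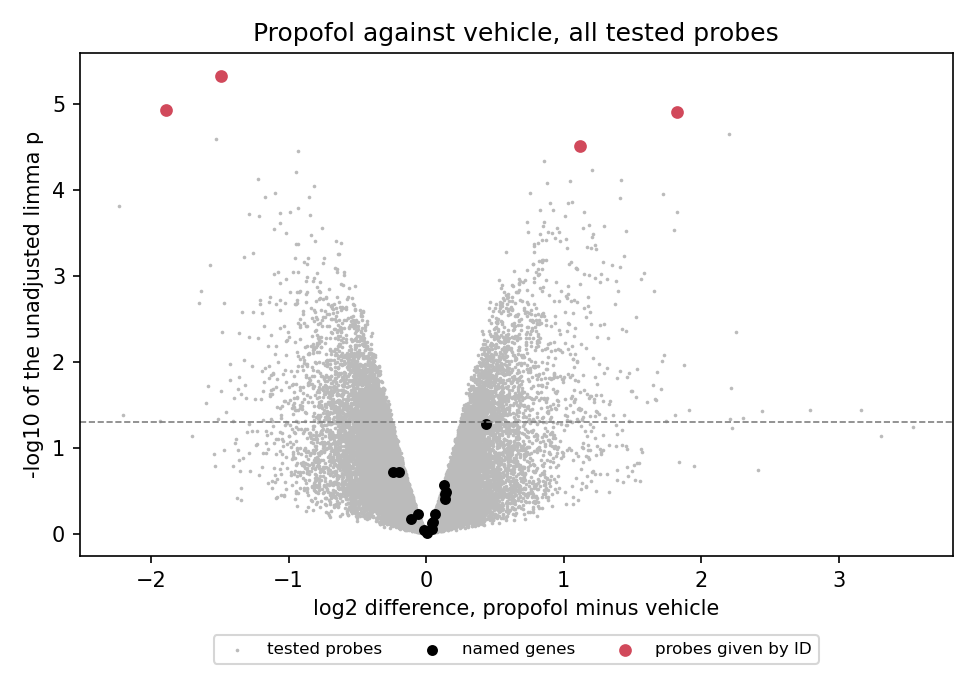
Log2 difference of propofol minus vehicle against the -log10 of the unadjusted limma p for the 47777 tested probes, with the 15 named genes in black and the 4 probes given by identifier in red. The dashed line marks an unadjusted p of 0.05, and 3756 probes lie above it.

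Classes of probes were compared by their shares at an unadjusted p under 0.05. Of the mRNA probes in the deposited value table, 21201 were tested, with 7.26% at that level, and 247 were higher and 226 lower by the unadjusted rule. Of 1836 probes whose names mark long intergenic non-coding RNA, 732 were tested, with 7.10% at that level, and 12 were higher and 11 lower. The other 25829 tested probes gave 8.38%, with 368 higher and 414 lower. In the deposited log2 values, with all probes of the value table, limma gave 0 probes past an adjusted p of 0.05, with 1368 at an unadjusted p under 0.05, and 327 probes were higher and 187 lower by the unadjusted rule. Its log2 differences correlated with those from the spot signals at r = 0.917 across 21201 probes, which are not independent replicates.

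The fixed lists of pathways and cell types could not be tested, since 2 of the 31 lists had a named member on the array and those had 1 each. Among the lists without a named member were those for activity-regulated genes, glucocorticoid-responsive genes, fatty acid oxidation and the markers of glia, vessels and interneurons.

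The arrays were alike in their levels, with correlations between pairs of arrays from 0.968 to 0.988. The vehicle arrays were all on slide 1 and the propofol arrays all on slide 2, so slide and treatment cannot be told apart in any difference given here. The share of probes well above background was 80.2% ± 2.5 (SD, n = 4) on the vehicle arrays and 75.3% ± 2.9 (SD, n = 4) on the propofol arrays, with an exact two-sided permutation p of 0.0857. The lowest spot signal was 3.30 to 3.93 units on the vehicle arrays and 4.44 to 7.60 units on the propofol arrays, with an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 arrays can give (0.143 after adjustment over the 10 array measures compared). The third principal component, with 13.9% of the variance, also separated the groups, with the same exact permutation p of 0.0286 and 0.143 after adjustment. There were 158 probes well above background on all 4 vehicle arrays and on no propofol array, and 0 probes with the reverse.

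Control spots named for mouse Gapdh and for mouse Pgk1, another glycolytic enzyme, carry the suffixes 3 and 5, read here as the 3′ and 5′ ends of the transcripts. The log2 signal of suffix 3 minus suffix 5 for Pgk1 was 8.53 ± 0.33 (SD, n = 4) in vehicle and 8.59 ± 0.28 (SD, n = 4) in propofol, with an exact permutation p of 0.771. For Gapdh it was -0.39 ± 0.26 (SD, n = 4) in vehicle and -0.17 ± 0.09 (SD, n = 4) in propofol, with an exact permutation p of 0.171. The first principal component of the tested probes held 29.7% of the variance between arrays and followed the Pgk1 contrast (Pearson r = 0.980, exact permutation p = 0.00015; Spearman rho = 0.976, exact permutation p = 0.0004). Without the 2 arrays farthest from the median contrast, that r was 0.969. Over the 4 measures correlated with the component, the adjusted p for the Pgk1 contrast was 0.0006 for r and 0.0016 for rho. With both measures centred on the mean of each slide, r was 0.981 over the 8 arrays (exact permutation within slides p = 0.00521; Spearman rho of ranks within slides = 0.900, exact permutation p = 0.0243), and 0.967 without the 2 arrays farthest from the median (exact permutation p = 0.0833).

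**Figure D3:**
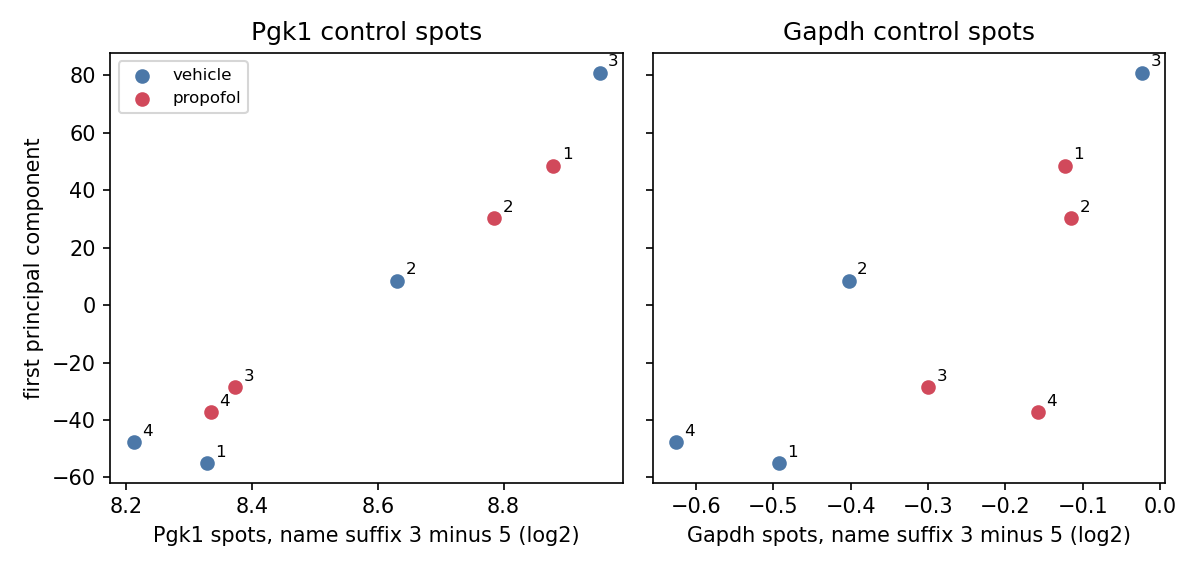
First principal component of the tested probes (arbitrary units) against the log2 difference between control spots of suffix 3 and suffix 5 for Pgk1 and for Gapdh, 1 point per array with its replicate number, vehicle in blue and propofol in red. Vehicle arrays lie at both ends of the component, from -55.0 to 81.0, with the propofol arrays between -37.3 and 48.6.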

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

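The splits of the arrays, the correlations with the first principal component and its share between groups were tests chosen after their results were seen. The tests of the detection limit, of the size of the fall and of array brightness were set before. Those of the limit and of the fall are read below with added conditions that their set rules did not hold.

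A value far from the other 3 of its group was found for 3 of the 54 groups of 4 values examined, where chance gives about 1 in 20. Hprt stood at 5.51 in vehicle replicate 1, against 5.28 to 5.30 in the other vehicle arrays. Tfrc stood at 4.67 in propofol replicate 1, against 5.25 to 5.34 in the other propofol arrays. Probe ASMM10P041006 stood at 0.55 in propofol replicate 4, against 0.15 to 0.18 in the other propofol arrays. No control spot that was well above background on all 8 arrays was apart between the groups in either direction. The 2 negative control probes among them were lower in propofol, by log2 differences of -0.55 (exact permutation p = 0.0857) and -0.53 (exact permutation p = 0.0571). Of the 13 other negative control probes, all but 2 were higher in propofol, by 0.05 to 0.52, and those 2 differed by -0.29 each. None of these 13 was well above background on all 8 arrays. The lowest spot signal was also higher on the propofol arrays, so the higher values near that floor are not separate evidence. The mouse suffix 3 spots of Gapdh and Pgk1 were higher, by 0.15 and 0.23 (exact permutation p = 0.0571 each). The human suffix 3 spots of Gapdh and Pgk1 differed by -0.08 and 0.06, and the rat suffix 3 spot of Gapdh by -0.14.

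For the comparison of propofol with vehicle, chance cannot be excluded by other splits of the 8 arrays. By the unadjusted rule, the real split had 1252 among the 46848 probes with a value on every array. Of the 35 splits, 10 gave at least that many, the real split included, and the highest other split had 3038. Past the adjusted threshold the real split gave 0 probes, which any of the 35 splits must reach or exceed, so that count tests nothing. The highest other split gave 744. The split with 744 calls set the 4 arrays lowest on the first principal component against the 4 highest. That component comes from these same probes and does not follow treatment, so the calls restate it and are not separate evidence of a structure. The third component, with 13.9% of the variance, did follow the groups, at 8.62 to 55.8 in vehicle and -40.2 to -12.6 in propofol (exact permutation p = 0.0286, adjusted 0.143), and slide follows them as well.

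The split with most calls follows the first principal component of the arrays. The treatment groups do not account for this component, since 0.501% of its variance lay between them. Array brightness as the whole cause is argued against by the partial correlation of the component with the Pgk1 contrast given brightness, 0.968, and at least 0.955 with any 1 array left out. Brightness alone followed the component at r = 0.747 (exact permutation p = 0.0232, adjusted 0.0408; rho = 0.833, exact permutation p = 0.0154), and at 0.787 without the 2 arrays farthest from its median (exact permutation p = 0.0833), so a part in it stays open. A candidate explanation is uneven coverage along transcripts, from RNA integrity or labelling. The Gapdh contrast, from other spots, followed the component at r = 0.767 (exact permutation p = 0.0306, adjusted 0.0408). Its rho was 0.857 (exact permutation p = 0.0107). Without the 2 arrays farthest from its median, r was 0.597 (exact permutation p = 0.214). Whether the correlation rests on those arrays or lost its p to the smaller number stays open. With both measures centred on the mean of each slide, r was 0.865 (exact permutation within slides p = 0.0156). The rho of ranks within slides was 0.7 (exact permutation p = 0.111), and r without 2 arrays was 0.722 (exact permutation p = 0.125).

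There were 158 probes detected on all 4 vehicle arrays and on no propofol array. Chance cannot be excluded, since 3 of the 35 splits, the real one among them, gave as many and the highest other split gave 219. The median of the other splits was lower, at 13.5. The other splits that gave as many had 219 and 174, and each put propofol replicate 4 with 3 of the vehicle arrays. The median log2 difference of the 158 probes was -0.70 (95% bootstrap interval over probes -0.79 to -0.67), and 30 of them differed by 1 or more. That interval describes the spread among probes measured on the same arrays, not the uncertainty between propofol and vehicle. The choice of these probes by detection on vehicle arrays alone also favoured a lower level in propofol. Their median vehicle level of -4.97 lies at the mean propofol detection limit of -4.95, too near background to bound a fall. A higher mean detection limit on the propofol arrays, against -5.42 on the vehicle arrays, and a fall of these transcripts cannot be told apart. The limits of single arrays overlapped, at -5.1 on vehicle replicate 1 and -5.2 on each of propofol replicates 3 and 4. By these limits, a higher limit alone does not account for the lack of detection on propofol replicates 3 and 4. Below the mean propofol limit lay 53.8% of the vehicle means, with an interval over probes from 46.2% to 61.4%. By the rules set before, that share counts for the limit. The median, short of a 2-fold fall beyond its interval, counts by them against a large fall. Those rules asked neither that the interval of the share clear an even split nor that a 2-fold fall stay above the limit. With these conditions added, neither test decides. Slide and treatment coincide, which keeps the limit and the fall both open.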

How the results depend on the processing

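The covariates from control spots and the fit without vehicle replicates 2 and 3 were chosen after seeing the data. In limma, 21 of 22 alternatives gave 0 probes past the adjusted threshold (smallest adjusted p from 0.0514 to 0.926), against 3 with normexp, run on the median signal because the files used hold no mean signal. The equal-variance test gave 176 probes at an unadjusted p under 0.05 and at least 2-fold, and 0 after adjustment; leaving out each array in turn gave 0 each time. The unadjusted rule gave 1278 probes, 400 with normexp, 447 in the deposited values (fewer probes tested), 2197 with no filter, 828 with probes well above background on all 8 arrays (fewer tested), 2380 with array weights, 2543 with the Gapdh contrast as covariate and 2197 without vehicle replicates 2 and 3 (fewer arrays). The 447 is from a part of the deposited probes, while the higher and lower counts for the deposited values in Results are from all of them. The number by the unadjusted rule ranged from 1162 to 1873 with 1 array left out. Except for the filters and left-out arrays, the cause was not tested. The share of these probes higher in propofol was 49.1%, but 64.3% with quantile normalization, 59.8% with the array median, 82.5% with normexp, 67.3% in that part of the deposited values, 67.6% with probes above background on all 8 arrays, 41.0% with the 75th percentile over those probes, 33.5% with array weights, 39.4% without vehicle replicate 3 and 30.97% without propofol replicate 4. The replicate block gave 0 probes past the adjusted threshold and 1436 by the unadjusted rule, and it changed no other call. Same-numbered arrays also held the same position on their slides, so the replicate block is a block of position as well. The correlations of deviations of same-numbered arrays were -0.33, 0.07, -0.11 and 0.22, and 1 of 4 vehicle arrays was closest to its own number. These values show no common pairing by number, but 4 pairs are too few to exclude one. Of the 15 named genes, 8 kept their sign in the 21 alternatives that gave them a value (the deposited table does not hold them), among them Tfrc (0.31 to 0.59), Actb (-0.38 to -0.15), Hsp90ab1 (0.05 to 0.21), Hprt (0.04 to 0.24), Gusb (0.05 to 0.23) and B2m (0.04 to 0.24), while Nono, Ppia, Rpl13a, Gapdh, Gk, G6pd2 and Tbp changed sign in at least 1. The 4 probes given by identifier kept theirs wherever they had a value, which their choice by separated groups and smallest p favours. Signal over background limits dim probes such as Ldhal6b, which kept its sign at -0.29 to -0.13 over the 21 alternatives. A slide block could not be fitted because each slide held 1 group, a sex covariate was not run because no sex-linked marker is named, list tests were not run for want of members, and the choices among probes of a gene changed nothing since each gene had 1.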

Other observations

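In the paragraph on probes low on 2 vehicle arrays, the tests of noise and of absence were chosen after the values were seen, and the test of position on the array was set before. The test of noise was first run on all 7 probes, where another pair of arrays gave 12, was then divided by level, and for the 4 brighter probes was last replaced by a ratio of gap to range, set beside that of probes picked the same way on other pairs.

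The differences of Gk and G6pd2 between propofol and vehicle depended on which control spots entered the fit, and also on single arrays. With the Pgk1 contrast as a covariate, chosen after seeing the data, the log2 difference of Gk was -0.03 with an SE of 0.14, against 0.04 with an SE of 0.25 without it, and that of G6pd2 was -0.04 with an SE of 0.17, against -0.11 with an SE of 0.25. With the Gapdh contrast in its place, also chosen after seeing the data, Gk differed by -0.22 with an SE of 0.25 and G6pd2 by 0.29 with an SE of 0.155. Tfrc differed by 0.44 (SE 0.20) with the Pgk1 covariate, by 0.35 (SE 0.23) with the Gapdh covariate and by 0.43 (SE 0.19) with neither. None of the 3 genes passed the adjusted threshold in limma in any of these fits.

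A set of 7 probes was low on vehicle replicates 2 and 3 alone, by a gap of at least 1.5 on the log2 scale to the other 6 arrays, which held both vehicle and propofol. For 3 of the probes, which were not well above background on those 2 arrays, noise near background stays open, since another pair of arrays gave 11 such probes. The other 4 were well above background on all 8 arrays with gaps from 2.67 to 5.38, while no other pair gave more than 2 such probes and their largest gap was 2.17. Noise in dim probes is argued against for these 4, since each gap was at least 5.40 times the probe's range over the other 6 arrays, where the 4 probes picked the same way on other pairs reached 3.31 times. A local flaw of the array surface shared by all 7 probes is argued against, since their mean distance stood at percentile 89.6 among 2000 random sets. The 4 brighter probes were not tested alone, so a flaw at some of them stays open. Absence of the transcripts from those samples stays open. Only 3 of the 7 probes were not well above background on both arrays, and the other 4 read from -5.36 to -2.56 there. Of the negative controls, which have no target, 2 reached levels up to -2.38 and the other 13 reached no more than -4.55, so levels of different probes do not settle it. A difference in sex or strain may give such a set and was not tested, because neither is in the labels and the probes have no gene name.

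Probes at least 4-fold above every other array numbered 57 on propofol replicate 1, 36 on propofol replicate 2 and 50 on vehicle replicate 3, and vehicle replicate 4 had 0. Probes at least 4-fold below every other array numbered 74 on vehicle replicate 3 and 12 on vehicle replicate 1, with at most 1 on each of the others. On propofol replicate 1, 39 of the 57 lay within 10 rows and columns of another of them, where random sets of the same number gave 18.1 on average and 30 at most. On propofol replicate 2 this held for 24 of the 36, where random sets gave 7.60 on average and 17 at most. On vehicle replicate 3 it held for 13 of the 50, where random sets gave 13.8 on average. Of the 15 negative control probes, 2 were well above background on all 8 arrays.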
